A study of Vitis vinifera with 11 samples.

How the data were processed

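Messenger RNA was sequenced from grapevine (Vitis vinifera) inflorescences, tendrils and leaves with single-end Illumina mRNA libraries, per the labels' protocols. The 11 libraries held 6 of inflorescences, 3 of tendrils and 2 of pooled leaves. Inflorescences came from 2 picovine lines, 06C021V0046 and 06C008V0003, at 3 successive nodes, numbered downward from the shoot tip. Tendrils at the same positions came from the control vine Pinot Meunier L2. The protocol text writes the first picovine line with another year prefix than the sample labels do, and the sample labels were followed.

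The deposited tables gave 1 RPKM value (reads per kilobase of gene and 1e6 mapped reads) for each of 25771 gene numbers in each library, and this unit was taken from the authors' file labels. Bowtie 0.12.7 and TopHat 1.2.0 were named in the submitters' processing notes. The genome build, the gene annotation and the counting tool were not given in the sources used here. Gene numbers were paired with names through the RefSeq table of the assembly ASM3070453v1, used for names only. That table held 18647 of the gene numbers (72.4%), and 309 genes had a symbol or synonym other than a locus number. No gene position is given because the build behind the values was not named. How reads shared between near-identical copies were counted was also not given, so values of the PR10, chalcone synthase (CHS1, CHS2) and AGAMOUS-like genes are uncertain as to the copy.

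Read depth was worked back from the RPKM values, because the values of a gene are whole multiples of the worth of 1 read in each library. All 24365 genes with a value above 0 came out as whole reads in every library (100%, tolerance 0.01 read). Where several read numbers suited a gene, the smallest were taken, so reads of low genes may be underestimated and their intervals too wide. Depth ran from 7.36 M reads (M, 1e6) in the tendril library of position 2 to 15.18 M in that of position 3. A gene of 1 kilobase with 3 reads had between 0.198 and 0.408 RPKM, depending on the library. Intervals at the 95% level and floors of 3 reads cover counting error only, and the reads carried no molecular identifiers.

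The main test was limma 3.58.1 in R 4.3.3, on log2(RPKM + 1), over 19761 genes with an RPKM of at least 1 in at least 2 libraries. One model over all 11 libraries held the 3 organ means at position 2 and a separate linear slope on node position in inflorescences and in tendrils. Variances were shrunk with a trend on mean expression, with 6 residual and 4.54 prior degrees of freedom. Adjusted p values are Benjamini-Hochberg values from this two-sided test, and genes were called at a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of genes with low values. Each tendril position had 1 library, so the error of the tendril slope rests on the scatter of the 3 tendril libraries about a line and on the other organs. The replicates of a position were different genotypes, so the spread between them holds both. The SD given for an organ is taken over its libraries of all nodes and genotypes, so it also holds changes between nodes. The picovine genotypes were compared in the 6 inflorescence libraries alone, with node position as a factor. The leaf pools of the 2 genotypes were set side by side without a test, 1 library each.

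Replicate 1 of inflorescences and of leaves was 06C021V0046, replicate 2 was 06C008V0003 in inflorescences and Pinot Meunier L2 in leaves, so the block used was genotype. Across genes, the difference between the picovine genotypes correlated between positions 1 and 2 (0.629), 1 and 3 (0.546) and 2 and 3 (0.689), so libraries of 1 genotype deviated together and the fit with the block is given where it changed a call. In that fit, inflorescences and tendrils are linked only through the leaf pools of 06C021V0046 and Pinot Meunier L2.

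Named genes followed a rule: among called genes with a mean of at least 5 RPKM in the higher organ or position, a name, and no overlap between the libraries compared, the 10 largest rises and 10 largest falls; every called member of the floral MADS-box and flowering lists, up to 15; and the 3 members with the largest change in each other list. A locus number was used for at most 2 genes each way. Genes outside the rule are named as such. The model, this rule, the alternatives and the list themes were set before the data were examined, with the exceptions that follow. Of 19 lists written as name patterns, 17 matched no gene because the naming table holds symbols without product names. Lists of symbols were therefore written once the table had been seen and before any comparison was computed, some on themes added at that point. Of 18 such lists, 14 had the 5 tested members needed for camera, which was run with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one, with adjustment over the 14 lists of a comparison. A gene was called organ-restricted with an RPKM of at least 1 in every library of an organ and under 0.5 in every other library.

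Each result was recomputed with pseudocounts of 0.1 and 5, without the filter, with a minimum of 5 RPKM, after quantile normalization, after median-ratio scaling, with the genotype block, with only the organs compared, with robust shrinkage, and without each library in turn. Without the tendril library of position 1 or 3, the tendril mean is the value of the position 2 library alone. For comparisons of tendrils with another organ, both fits are thus the same check, resting on the shallowest library (7.36 M reads). limma voom on the worked-back reads was added after the data were seen. On simulated read numbers for all 19761 genes with a dispersion of 0.0603 taken from the residuals, 57% of 100 genes changed by 1 on the log2 scale and 100% of those changed by 2 were recovered between inflorescence and tendril. The shares were 26% and 98% for inflorescence against leaf, 26% and 97% for tendril against leaf, 95% and 100% for the inflorescence slope, 49% and 100% for the tendril slope, 14% and 96% for the slope difference, and 19% and 99% for the picovine genotypes. At a dispersion of 0.1, the shares at a change of 1 fell to between 4% for the slope difference and 74% for the inflorescence slope. The simulations gave every gene the same dispersion, drew libraries independently without a genotype effect, and changed only genes above a minimum of reads. They do not describe the recovery of low genes, or recovery where libraries of a genotype deviate together. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.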

Results

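Transcript levels were compared between the inflorescences, tendrils and leaves of grapevine shoots at successive nodes. Picovines are dwarf vines, and here they supplied the inflorescences of nodes 1, 2 and 3 from the apex, with 1 library from 06C021V0046 (replicate 1) and 1 from 06C008V0003 (replicate 2) at each node. The control vine Pinot Meunier L2 supplied 1 tendril library per node. Leaves of the 3 nodes had been pooled, giving 1 library from 06C021V0046 and 1 from Pinot Meunier L2. The sample labels place both pools opposite inflorescences, whereas the collection protocol names tendrils, not inflorescences, for Pinot Meunier L2, so the position of its leaves is uncertain. Organ and genotype therefore changed together between inflorescences and tendrils, and only the 2 leaf pools link the genotypes. Depth was 11.36 to 14.55 M reads (M, 1e6) in inflorescences, 7.36 to 15.18 M in tendrils, and 9.21 and 14.99 M in the leaf pools. Between 17064 and 18387 genes had an RPKM of at least 1 in a library. Across genes, which are not independent replicates, the 2 picovine libraries of a position correlated at 0.959, 0.970 and 0.954 (Pearson, log2 scale).

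**Figure D1:**
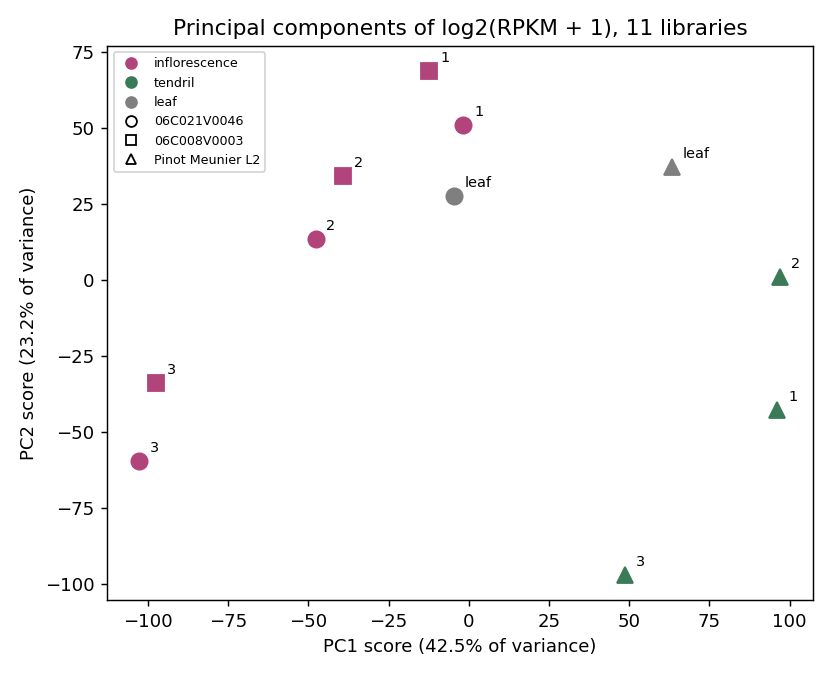
Scores of the 11 libraries on the first components of log2(RPKM + 1), coloured by organ, with marker shape for genotype and the node position beside each point. Component 1 (42.5% of variance) placed the inflorescences between -102.65 and -1.68 and the tendrils between 48.76 and 97.12, with the picovine leaf pool at -4.52 and the Pinot Meunier L2 leaf pool at 63.37.

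Inflorescences were first compared with tendrils of the same nodes, to ask which transcripts mark reproductive structures. Of the floral organ genes, 6 were abundant in inflorescences and near the detection floor in tendrils. MADS9, the grapevine PISTILLATA of petal and stamen identity, stood at 695 ± 138 RPKM in inflorescences (SD, n = 6), with 2 reads in all 3 tendril libraries, a ratio of 9722 (95% counting interval 2691 to 80275). Its partners TM6 and AP3 stood at 253 ± 66.6 and 81.2 ± 19.5 RPKM, with ratios over tendrils of 418 (271 to 685, on 20 reads) and 3138 (563 to 123964, on 1 read). AG, of the class that specifies stamens and carpels, reached 209 ± 118 RPKM, with a ratio of 2878 (797 to 23762, on 2 reads). MADS1, an AGAMOUS-like gene, had 97.46 ± 45.48 RPKM and a ratio of 2050 (568 to 16931, on 2 reads), and the SEPALLATA gene MADS2 had 197 ± 19.9 RPKM and a ratio of 1173 (539 to 3196, on 6 reads). These 6 genes differed with adjusted p between 8.83e-10 (MADS9) and 1.3e-07 (AP3), and kept the call with the genotype block, at 0.000149 and 0.0019, and in every other setting run. That block links inflorescences and tendrils only through the leaf pools, where MADS2 and AP3 had no read. MADS9 and TM6 reached at most 0.630 and 0.720 RPKM there. For such genes the block had almost nothing to correct, so the kept call says little about genotype.

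Of the other flowering genes, several had reads well above the floor in both organs. FT, the mobile flowering signal, averaged 67.0 ± 27.8 RPKM in inflorescences and 7.92 ± 4.35 in tendrils (log2 change 2.94 ± 0.29 SE), and MADS3 averaged 94.7 ± 19.6 and 10.58 ± 4.24 (3.08 ± 0.29). MADS5, the ovule identity gene AGL11, stood at 7.44 ± 4.69 RPKM against 5 tendril reads, a ratio of 46.8 (20.0 to 144). The reverse held for MADS8, the grapevine SOC1, which averaged 9.20 ± 3.64 RPKM in inflorescences and 50.7 ± 15.9 in tendrils (-2.36 ± 0.28). VFUL-L, a FRUITFULL-like gene, averaged 34.1 ± 7.23 and 71.6 ± 4.68 (-1.08 ± 0.24), and AP1, named outside the rule after its values were seen, averaged 141 ± 17.8 and 193 ± 93.3 and was not called (adjusted p = 0.385). AP2 rose by 1.15 ± 0.33. With the genotype block, the changes of FT, MADS3, MADS5, MADS8, VFUL-L and AP2 were 3.29, 3.73, 2.79, -2.81, -2.24 and 2.35, as large as or larger than without it, but their calls ended (adjusted p 0.0559, 0.0618, 0.117, 0.0797, 0.0613 and 0.237). Without the tendril library of position 1 or 3, VFUL-L reached 0.085 and 0.0858, and AP2 0.437 and 0.436. Of the 11 floral MADS-box genes, 8 rose and 2 fell, and 10 were called when adjusted over the list alone. The list stood above other genes in camera (adjusted p = 1.87e-05; adjusted p = 0.524 with an estimated correlation; 7.36e-09 with the block).

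**Figure D2:**
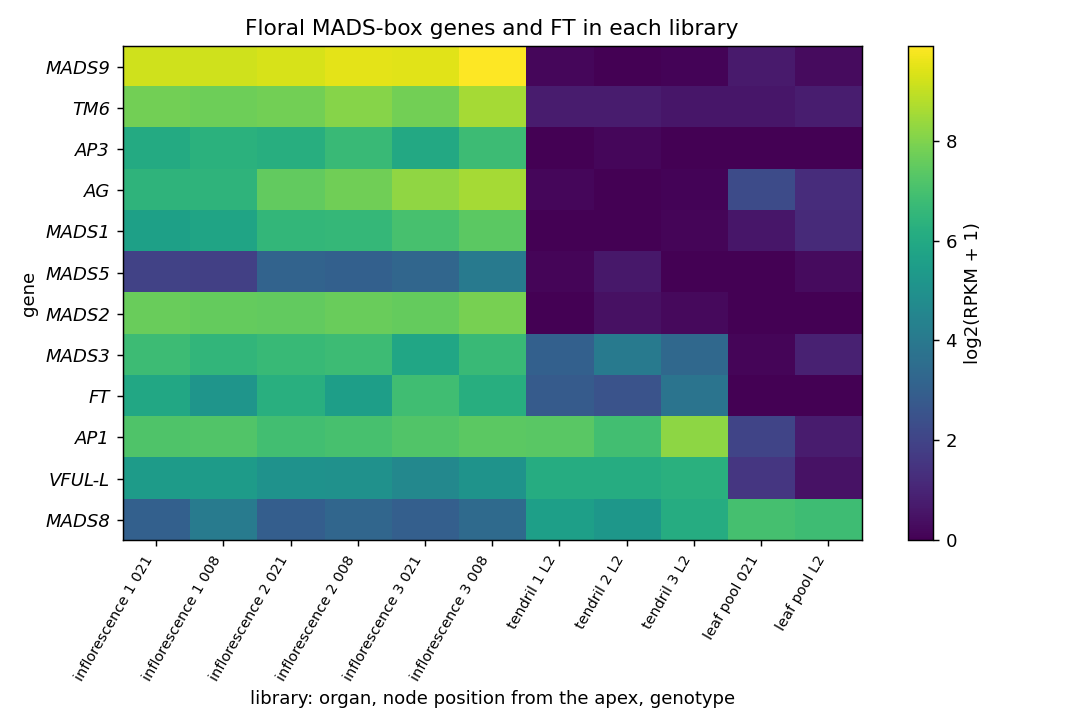
Heat map of log2(RPKM + 1) for 12 flowering genes (vertical axis) in the 11 libraries (horizontal axis), with colour giving the level and the last word of each library label its genotype. MADS9, TM6, AP3, AG, MADS1 and MADS2 are bright in the 6 inflorescence libraries and dark in the 3 tendril libraries, whereas AP1 is bright in both organs and MADS8 is brightest in the leaf pools.

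Of 18 defence genes, 12 rose in inflorescences and none fell (14 called when adjusted over the list alone), and 1 was called with the genotype block. PR1, a pathogenesis-related protein, averaged 859 ± 395 RPKM in inflorescences and 3.93 ± 0.69 in tendrils (log2 change 7.35 ± 0.44, adjusted p = 5.3e-06, 0.0407 with the block). PR10.3 rose by 4.37 ± 0.62 and PR10.2 by 3.26 ± 0.51, and with the block their changes were 2.12 and 1.59 and both calls ended (0.605 and 0.705). In the leaf pools PR1, PR10.3 and PR10.2 stood at 3338, 143 and 823 RPKM in 06C021V0046 and at 848, 44.5 and 286 RPKM in Pinot Meunier L2. The defence list was called by camera (adjusted p = 0.00151; adjusted p = 0.527 with an estimated correlation; 0.0381 with the block). All 3 heat shock genes fell, and none was called with the block. HSP101, a chaperone that dissolves protein aggregates, averaged 8.76 ± 4.91 RPKM in inflorescences and 423 ± 172 in tendrils (-5.57 ± 0.60; with the block -2.60, adjusted p = 0.234). HsfA2, a heat stress transcription factor, averaged 20.8 ± 2.36 and 120 ± 10.55 RPKM, and BiP 1.49 ± 0.90 and 6.28 ± 0.92. The fits of HsfA2 and BiP changed sign with the block, to 0.65 and 0.45 on the log2 scale (adjusted p 0.56 and 0.793), and both missed the threshold without the tendril library of position 1 (0.0525 and 0.0646) or 3 (0.053 and 0.0649), BiP also with a pseudocount of 0.1 (0.064). In the leaf pools these genes stood at 25.7, 7.32 and 0 RPKM in 06C021V0046 and at 251, 72.4 and 3.42 RPKM in Pinot Meunier L2.

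**Figure D3:**
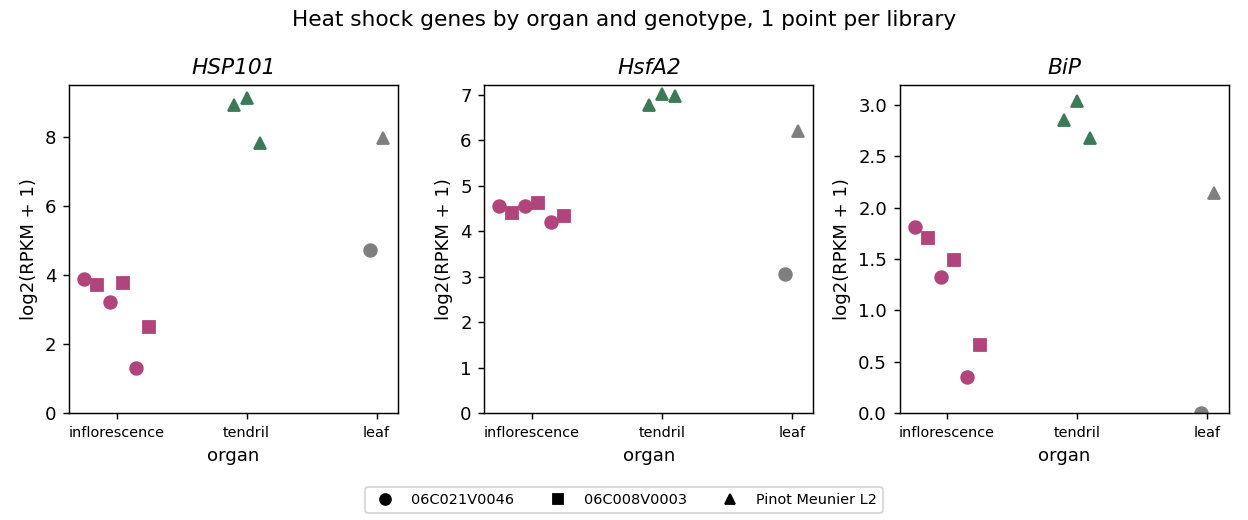
Levels of HSP101, HsfA2 and BiP as log2(RPKM + 1) on the vertical axis, by organ on the horizontal axis, with 1 point per library and marker shape for genotype. For each gene the Pinot Meunier L2 leaf pool lies above the 06C021V0046 leaf pool, and the 3 Pinot Meunier L2 tendrils lie above the 6 picovine inflorescences.

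Of 10 aquaporins, which pass water across membranes, 4 were lower in inflorescences than in tendrils and none higher (5 called when adjusted over the list alone), and 0 were called with the block in limma. TIP1;1 averaged 86.5 ± 61.5 RPKM in inflorescences and 597 ± 137 in tendrils (-3.12 ± 0.61), PIP2;3 115 ± 37.2 and 437 ± 70.1, and TIP1;2 484 ± 234 and 1295 ± 285. With the block their log2 changes were -0.98, 0.01 and -1.01 (adjusted p 0.365, 0.998 and 0.532). TIP1;1 missed the threshold without the tendril library of position 1 or 3 (0.0609, 0.0616), as did TIP1;2 (0.145 in both). The aquaporin list was called (adjusted p = 0.00326; adjusted p = 0.661 with an estimated correlation; 0.453 with the block). Among 5 gibberellin genes, GA20ox1, an enzyme of gibberellin synthesis, was higher in inflorescences, with 14.8 ± 15.4 RPKM and a ratio of 138 (53.9 to 507, on 4 tendril reads). GA2ox6, a gibberellin-inactivating enzyme, was lower, with 0.111 ± 0.134 RPKM against 7.34 ± 8.52, and so was VVGAI1, a DELLA repressor of the hormone response, with 3.07 ± 2.67 against 36.7 ± 32.6. The organs overlapped for VVGAI1, with 3.21 RPKM in the tendril library of position 3 and 7.99 and 4.26 RPKM in inflorescences of position 1. The log2 changes of GA20ox1, GA2ox6 and VVGAI1 were 2.95, -2.43 and -2.69. With the block, which ended the calls, they were 2.07, -1.86 and -0.21 (adjusted p 0.212, 0.332 and 0.972). The 06C021V0046 leaf pool held these genes at 2.26, 0.184 and 2.10 RPKM, and that of Pinot Meunier L2 at 0.521, 0.904 and 13.6. These leaf differences go the same way as those between the organs, so organ and plant material cannot be told apart for these genes. The 2 locus numbers with the largest changes were LOC100242221, with 832 ± 1013 RPKM in inflorescences and 1 tendril read (ratio 41327, 7417 to 1632341), and LOC100268056, with 1.18 ± 0.79 RPKM in inflorescences and 798 ± 295 in tendrils.

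In total 6737 of 19761 genes differed between inflorescences and tendrils, 4445 higher and 2292 lower, and 4137 by at least 2-fold. The share of higher genes was 66.0% as deposited, 51.9% after quantile normalization and 49.2% after median-ratio scaling. The median change of all genes was 0.21 as deposited, 0.05 and 0.01 after those scalings, so small rises stand against that shift. With the genotype block 77 genes were called, 70 of them among the 6737. Of 56 named genes called, 47 lost the call with the block and 19 without 1 library. MADS9, AG, MADS2, PR1, TM6, MADS1, AP3, LOC100242221 and LOC100268056 kept it in every setting. With the block the change of PR1 went from 7.35 to 5.52 and that of LOC100268056 from -8.52 to -5.02, and the latter stood at 38.4 RPKM in the 06C021V0046 leaf pool and 371 in that of Pinot Meunier L2. Without the tendril library of position 1 the count was 3699, and without that of position 3 it was 3685.

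Inflorescences were next compared with the leaf pools. The floral organ genes again led. MADS9 was higher by 8.92 ± 0.21 on the log2 scale, with a ratio of 1811 (919 to 4195, on 8 leaf reads), and TM6 by 7.25 ± 0.24. MADS2, AP3 and FT had no read in either leaf pool and were at least 1748-fold, 780-fold and 450-fold higher against a floor of 3 reads over both pools. AP1, which promotes floral meristem identity, averaged 141 ± 17.8 RPKM in inflorescences and 1.87 ± 1.65 in leaves (5.75 ± 0.35), and AG averaged 2.63 ± 1.72 in leaves (5.73 ± 0.27). MADS8 was the one floral MADS-box gene that fell, to 9.20 from 119 ± 8.41 RPKM in leaves (-3.62 ± 0.32). Of the 11 members, 10 rose and 1 fell (11 called when adjusted over the list alone), and camera called the list with the preset and with the estimated correlation (adjusted p = 1.44e-18 and 0.0341). GA3ox1, of gibberellin synthesis, rose by 2.20 ± 0.24.

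Among defence and photosynthesis genes, those called were lower in inflorescences than in leaves. CHI1B and chit1a, both chitinases, averaged 32.6 ± 20.3 and 11.9 ± 4.94 RPKM in inflorescences and 359 ± 256 and 93.6 ± 43.0 in leaves, and PR-1 fell by 3.27 ± 0.29. Of 18 defence genes, 8 fell and none rose (11 called when adjusted over the list alone), with adjusted p = 0.00181 for the list and adjusted p = 0.29 with an estimated correlation. Of 5 photosynthesis genes, NDHM and PSBP1 fell (4 called when adjusted over the list alone), and the list was called (adjusted p = 0.019; adjusted p = 0.29 with an estimated correlation). NDHM, a subunit of the chloroplast NDH complex, averaged 7.93 ± 2.73 RPKM in inflorescences and 31.9 ± 6.21 in leaves, and PSBP1, of photosystem II, 177 ± 86.5 and 487 ± 212. PSBP1 missed the threshold with the block (0.414), without the filter (0.0579), without the Pinot Meunier L2 leaf pool (0.313), without the second replicate of position 1 (0.0611) or the first of position 2 (0.0626), and without the first or second of position 3 (0.0587 and 0.0699). F3'5'H, which hydroxylates flavonoids, fell by 2.84 ± 0.30. VvCASPL2C1, of the Casparian strip family, fell by 2.51 ± 0.31.

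In all, 2556 genes differed between inflorescences and leaves, 1065 higher and 1491 lower. With the block, which leaves only the libraries of 06C021V0046 to carry the contrast, 1283 genes were called, 1051 of them shared with the first count. Without the Pinot Meunier L2 leaf pool the count was 1174. Of 41 named genes called, 11 lost the call with the block and 13 without 1 library.

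Tendrils were then compared with leaves. AP1 and VFUL-L marked tendrils, with 193 ± 93.3 and 71.6 ± 4.68 RPKM (n = 3) against 1.87 ± 1.65 and 1.18 ± 1.11 in leaves (n = 2), log2 changes of 6.10 ± 0.39 and 5.16 ± 0.31. FT had no read in leaves and was at least 53.3-fold higher in tendrils. GA3ox1 rose by 3.37 ± 0.27. GRIP68 averaged 610 ± 457 RPKM in tendrils and 26.8 ± 6.397 in leaves. AG and AP2 fell, by 1.69 ± 0.30 and 1.67 ± 0.43. With a pseudocount of 5 the change of AG was -0.57 and its call ended (adjusted p = 0.117), and AP2 missed the threshold without the Pinot Meunier L2 leaf pool (0.163) or the tendril library of position 1 or 3 (0.258 in both). MADS8 also fell, by 1.26 ± 0.36, and lost the call with the block, where the change was -1.19 (0.12), without either leaf pool (0.231 and 0.0924), without any 1 tendril library (0.0551, 0.0762 and 0.0561 for positions 1, 2 and 3), and without any 1 inflorescence library of position 2 (0.0599 and 0.0613) or 3 (0.0548 and 0.0545). Of the 11 floral MADS-box genes, 3 rose and 2 fell (6 called when adjusted over the list alone), and the list was not called (adjusted p = 0.167).

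The defence genes called were all lower in tendrils than in leaves. PR1 averaged 3.93 ± 0.69 RPKM in tendrils, 3338 in the 06C021V0046 leaf pool and 848 in the Pinot Meunier L2 leaf pool (-8.43 ± 0.57, adjusted p = 1.99e-05). PR10.2 fell by 4.54 ± 0.66, CHI1B by 4.58 ± 0.49 and PR-1 by 3.49 ± 0.33. Of the 18 genes, 12 fell and none rose (13 called when adjusted over the list alone), with adjusted p = 1.38e-08 for the list and adjusted p = 0.257 with an estimated correlation. MLO7 and MLO11, of the powdery mildew susceptibility family, fell by 2.23 ± 0.32 and 2.08 ± 0.33. CWINV, a cell wall invertase, fell from 20.6 ± 10.93 RPKM in leaves to 0.702 ± 0.135. Of 10 aquaporins, only TIP1;2 was called, with 1295 ± 285 RPKM in tendrils and 351 ± 5.14 in leaves, and without the tendril library of position 1 or 3 it reached 0.186 and 0.187. It also missed the threshold without the leaf pool of 06C021V0046 (0.169) or of Pinot Meunier L2 (0.095), or without the first replicate of inflorescence position 2 (0.054). The aquaporin list was called upward (adjusted p = 0.0142; adjusted p = 0.794 with an estimated correlation; 0.188 after quantile normalization).

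With only tendril and leaf libraries in the fit, adjusted p was 0.0509 for FT and CWINV, 0.0654 for CHI1B, 0.0504 for PR-1, 0.112 for AG, 0.281 for AP2, 0.175 for MADS8, 0.197 for TIP1;2 and 0.157 for GRIP68. MADS8 also missed the threshold with a pseudocount of 0.1 (0.0511), without the filter (0.0606) and with median-ratio scaling (0.0767), and TIP1;2 without the filter (0.0655). In all, 2490 genes differed between tendrils and leaves, 572 higher and 1918 lower. The share of higher genes was 23.0% as deposited, 42.3% after quantile normalization and 37.4% after median-ratio scaling, and the median change of all genes was -0.14, 0.05 and 0.03. With the block, which leaves Pinot Meunier L2 alone to carry the contrast, 1342 genes were called, and with only the 5 tendril and leaf libraries in the fit 258 were. The count was 1159 without the 06C021V0046 leaf pool, 1433 without the tendril library of position 1 and 1427 without that of position 3. Of 43 named genes called, 10 kept the call in every setting, among them AP1, VFUL-L, GA3ox1, PR1, PR10.2, MLO7 and MLO11.

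Within inflorescences, the change per node from position 1 to 3 was tested. CHI4C, a chitinase, averaged 1.54, 44.5 and 247 RPKM at positions 1, 2 and 3 (log2 slope 3.17 ± 0.36 SE per node, n = 6 libraries, adjusted p = 0.00176). SWEET15, a sugar exporter, averaged 2.02, 58.8 and 198 RPKM (3.04 ± 0.39, adjusted p = 0.00268), the hexose transporter HT5 2.68, 7.04 and 52.1, and the polyol transporter PMT2 0.476, 1.99 and 18.9. GA20ox1 averaged 0.730, 9.92 and 33.7 RPKM (2.16 ± 0.23, adjusted p = 0.00131). Slopes of CHI4C, SWEET15, GA20ox1, HT5 and PMT2 kept the call in every setting, as did the fall of LOC100265128 (134, 5.44 and 0.214 RPKM). Among floral MADS-box genes, AG averaged 86.3, 198 and 344 RPKM (0.99 ± 0.17), MADS1 50.6, 93.1 and 149 (0.76 ± 0.15) and MADS5 2.76 and 7.57 at positions 1 and 2, with 8.50 and 15.5 in the libraries of position 3 (0.87 ± 0.18; adjusted p = 0.117 with a pseudocount of 0.1). These 3 of 11 members rose and none fell (3 called when adjusted over the list alone). MYB24, a transcription factor of late stamen development, was near 0 at positions 1 and 2 and averaged 34.8 RPKM at position 3 (2.39 ± 0.50). MYC1, a flavonoid regulator, fell from 40.2 to 3.84 RPKM (-1.52 ± 0.41), CIPK03 from 163 to 41.2 (-0.97 ± 0.19) and VvCASPL2C1 from 26.7 to 4.35 (-1.18 ± 0.19).

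These slopes lean on the end positions, which have 2 libraries each. Without the first or second replicate of position 3, adjusted p values were 0.0504 and 0.0609 for AG, 0.0656 and 0.0723 for MADS1, 0.107 and 0.0693 for MYB24, 0.163 and 0.109 for MYC1, and 0.118 and 0.0676 for CIPK03. MADS5 reached 0.0835 without the second, and VvCASPL2C1 0.0522 without the first. Without the first or second replicate of position 1 they were 0.0583 and 0.0636 for MADS1, 0.0659 and 0.081 for MADS5, and 0.125 and 0.0865 for MYC1. Without the second alone, AG reached 0.0534, MYB24 0.0505 and VvCASPL2C1 0.0501, and without the first CIPK03 reached 0.0585. MYC1 also reached 0.056 without the first replicate of position 2, 0.0606 with a pseudocount of 5, 0.0668 without the filter and 0.0503 for position 3 against position 1. Of 18 defence genes 5 rose and 1 fell (6 called when adjusted over the list alone), and of 18 sugar transport and invertase genes 5 rose and 1 fell (7). No list was called by camera in limma at an adjusted p of 0.05, the lowest being sugar transport and invertase (0.0889, and an adjusted p of 0.744 with an estimated correlation). In all, 2960 genes had a slope, 1252 rising and 1708 falling, and 4588 with the block. Which direction was the more frequent depended on the setting, with 1595 rising and 1469 falling after median-ratio scaling, and 1033 and 994 without the filter. The count was 153 (133 rising) and 217 (178 rising) without the first and second replicate of position 3, 557 (342) and 397 (285) without those of position 1, and 1837 (856) without the first replicate of position 2. It was 4520 without the tendril library of position 1 or 3 and 4529 without that of position 2. Of 33 named genes called, 27 lost the call without 1 library.

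Only a straight change along the nodes was tested in tendrils. Across genes, their libraries of positions 2 and 3 correlated at 0.861, below positions 1 and 3 (0.938) and 1 and 2 (0.955). The tendril libraries thus did not line up in node order. With 1 library per node, and position 2 the shallowest, a course along the nodes cannot be told from variation between libraries. A change that turned at position 2 would be missed. An unadjusted p under 0.05 was reached by 971 of 19761 genes, no larger a share than that threshold passes by chance. Along tendrils no gene had a called slope in limma, and voom on the worked-back reads also called 0. Without the tendril library of position 1 the count was 1180, without that of position 2 it was 1, and without that of position 3 it was 27, each from 2 libraries whose spread was assumed to equal that of the other organs. The slopes of inflorescences and tendrils differed for 3 genes, all steeper in inflorescences, against 796 with an unadjusted p under 0.05, again no larger a share than by chance. LOC100242221 averaged 54.7, 412 and 2030 RPKM along inflorescences and had 1 tendril read. GeneID100258942 averaged 5.61, 25.4 and 148 RPKM along inflorescences and stood at 5.36, 4.34 and 3.58 in tendrils. LOC100267971 averaged 0.997, 8.99 and 46.7 RPKM and had no tendril read, so for it and LOC100242221 the difference restates the inflorescence slope. The count was 0 without the second replicate of position 1 or either of position 3, and 1 without the first replicate of position 1. It was 7 without the first replicate of position 2, 46 without the second, and 153 and 170 without the tendril library of position 1 or 3.

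The series title asks for messages found in floral development alone. Restricted to inflorescences were 42 genes, against 5 restricted to tendrils and 40 to leaves, from 6, 3 and 2 libraries. A gene thus had more chances to miss the minimum in inflorescences, but fewer other libraries in which to reach 0.5 RPKM. The highest by mean level were LOC100242221 (832 RPKM), LOC100249955 (747 ± 586), MADS2 and AP3. LOC100249955 ranged from 7.59 to 1500 RPKM within inflorescences. LOC100252519 led the tendril set at 3.82 ± 0.47 RPKM and LOC100244179 the leaf set at 33.0 ± 8.68. PALM1, a regulator of leaf form, was restricted to leaves at 6.26 ± 5.79 RPKM. MADS9, TM6 and AG were kept out of the inflorescence set by leaf or tendril values of up to 0.630, 0.720 and 3.85 RPKM. A limit of 0.1 in the other organs left 11, 0 and 2 genes. Without the second replicate of inflorescence position 1 the inflorescence count was 73. The tendril count was 38 without the Pinot Meunier L2 leaf pool and 29 without the tendril library of position 2. The leaf count was 60 without the second replicate of inflorescence position 1, 71 without the 06C021V0046 leaf pool and 89 without that of Pinot Meunier L2.

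Between the 2 picovine genotypes, 3892 genes differed in inflorescences, 2161 higher in 06C008V0003 and 1731 lower. Chosen after their values were seen, TIP1;1 stood at 122, 128 and 170 RPKM along the nodes of 06C021V0046 and at 23.6, 30.9 and 44.0 in 06C008V0003 (log2 change -2.09 ± 0.12, adjusted p = 0.000573). CHI4C was lower in 06C008V0003 by the same test (-1.53 ± 0.20), with 66.9 and 22.0 RPKM at position 2 and 398 and 95.0 at position 3. CIPK14 was higher, with 48.4 and 68.7 RPKM at position 1 and 25.2 and 73.1 at position 3 (0.90 ± 0.19). This fit had 2 residual degrees of freedom and drew 4.80 more from the shrinkage of variances. With no filter the prior fell to 1.52 and 11 genes were called, and with no position term 13 were. Which direction was the more frequent also depended on the libraries. With position as a factor, leaving out either library of a position takes that pair out of the comparison, so both fits give the same estimates. Without the first or second replicate of position 2, 43 genes were higher in 06C008V0003 and 211 lower, or 48 and 235 (254 and 283 in all). Without those of position 3 they were 238 and 681, or 193 and 659 (919 and 852), and without those of position 1, 1099 and 1257, or 1097 and 1267 (2356 and 2364). After quantile normalization 2150 were higher and 2130 lower.

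The leaf pools of 06C021V0046 and Pinot Meunier L2, 1 library each and so without a replicate check, differed at least 2-fold for 2523 of 15149 genes with 5 RPKM or more in either. Of these, 1654 were higher in Pinot Meunier L2 and 869 in the picovine. HSP101 and HsfA2 were the genes with a symbol furthest toward Pinot Meunier L2, at the 99.6 and 99.5 percentile of all differences. HPLA, a lyase of the oxylipin pathway, stood at 19.1 RPKM in the picovine leaf and 157 in that of Pinot Meunier L2. Toward the picovine lay GFH2 (61.8 and 7.18 RPKM), PR1 (3338 and 848), RD22-C (194 and 49.7) and GCAT (1498 and 395).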

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

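Of the tests below, those of picovine against Pinot Meunier L2 material and of inflorescence tissue in the picovine leaf pool were chosen only after the result was seen, and in the test of developmental stage the positions other than 2 were looked at afterwards. A test of the difference itself singled out 3 genes whose change per node differed between inflorescences and tendrils, but LOC100242221 had 1 tendril read and LOC100267971 none, so for both the test restates the slope in inflorescences. The log2 difference was 2.58 for LOC100242221 (adjusted p = 0.0414, limma, 6 and 3 libraries). For GeneID100258942 it was 2.49 (adjusted p = 0.0153). For LOC100267971 it was 2.29 (adjusted p = 0.0217). With voom on the worked-back reads, adjusted p was 1.0, 0.167 and 1.0 for the 3 genes, and without the second inflorescence replicate of position 3 it was 0.0606 for each.

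The first pattern weighed was the wide difference between inflorescences and tendrils, in which organ and genotype changed together. Of 84 splits of the 9 libraries into groups of 6 and 3, only the real one gave as many genes (1 split). It gave 7005 genes in a model with a common slope, and the highest other gave 31. The splits take libraries as exchangeable, but those of 1 genotype deviated together and all tendrils were of 1 genotype. The splits therefore cannot exclude chance, and a genotype difference also stays open. Of the rise of 8 floral MADS-box genes over tendrils on the log2 scale, the picovine leaf pool showed a median share of -0.010 (from -1.087 for MADS3 to 0.295 for AG), which argues only against plant material that raises these genes in leaves too. With 6 of the 8 under 1 RPKM in both leaf pools, a difference confined to organs that express them stays open, since tendrils came from Pinot Meunier L2 alone. For the 3 heat shock genes, the ratio of the median leaf difference to the median organ difference was 1.27. The picovine leaf pool lay below that of Pinot Meunier L2 by 3.24 (HSP101), 3.14 (HsfA2) and 2.14 (BiP, at 0 RPKM in the picovine pool) on the log2 scale. Inflorescences lay below tendrils by 5.57, 2.48 and 1.63. The leaf difference was thus larger than the organ difference for HsfA2 and BiP, and smaller for HSP101. A difference of plant material or of its growth, not tied to the organ, could account for HsfA2 and BiP. For HSP101 it would cover only part of the fall if its size were the same in every organ, which was not tested. This rests on 1 leaf library of each genotype. Over all called genes the ratio was 0.401, with 77.6% going the same way in leaves. Leaf differences of randomly drawn genes, set against the directions of the called genes, gave 50.3%, a share fixed in advance by the random pairing. Agreement among genes not called was not computed. For the called genes organ and plant material cannot be told apart, because each organ but the leaf came from other genotypes.

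The second pattern was the presence of AG and AP1 reads in the picovine leaf pool, 30 and 32 reads, or 2.00% (95% counting interval 1.35 to 2.86) and 2.25% (1.54 to 3.18) of the level in inflorescences of that genotype, while the Pinot Meunier L2 leaf pool held 18 and 12 reads. Inflorescence tissue among the leaves would bring its other abundant transcripts at the same share. The highest share among MADS9, MADS2, TM6 and AP3 was 0.243% (TM6, 0.0788 to 0.566), MADS9 stood at 0.0989% (0.0321 to 0.231), and MADS2 and AP3 had no read (upper limits 0.158% and 0.413%), and MADS1 stood at 0.558% (0.205 to 1.21), still below the interval of AG, which argues against such tissue as the whole source. VFUL-L had 37 reads in that leaf pool, 1.96 RPKM against 42.3, 32.2 and 23.3 RPKM in inflorescences of the genotype. Reads of related genes counted toward AG and AP1, and low transcription of both in leaves, were not tested.

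The third pattern was the difference between the picovine genotypes in inflorescences. The real split gave 3892 genes and was the only 1 of 10 splits with as many, the highest other giving 0, but 10 splits are too few for a share under 0.05. If the genotypes stood at different stages at the same node, their difference should follow the change between nodes. At position 2 the correlation across genes was -0.344, past the bound of 0.3 set beforehand, whereas at positions 1 and 3 it was -0.100 and -0.024, and among the called genes it was -0.392, -0.418 and -0.073 at positions 1, 2 and 3, so stage and genotype cannot be told apart with 1 library of each genotype per node. Of the 3892 genes, 527 also had a slope, against 583 for independent lists. The slope fit held no genotype term, so a genotype difference widened the error of that gene's slope. The overlap therefore cannot decide on stage.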

How the results depend on the processing

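Only voom on the worked-back reads was chosen after the result was seen. With the genotype block, 77 genes differed between inflorescence and tendril, 1283 between inflorescence and leaf, 1342 between tendril and leaf, 4588 had an inflorescence position slope and 6 a difference of the position slopes. Contrasts within 06C021V0046 and within Pinot Meunier L2 gave the same 1283 and 1342. They restate the block fit over all 11 libraries and are no separate check. The estimate of inflorescence against tendril turned positive with this block for HsfA2 (0.654), VVSUC27 (0.056), LAR2 (0.486), 4CL (0.261), BiP (0.449) and PIP2;3 (0.006). It rests there on the leaf pools, 1 per genotype. For PL1, inflorescence against tendril was 0.317 without tendril position 1 and 0.317 without tendril position 3, and ran from -2.653 to 0.317 over all libraries left out. Requiring at least 2-fold left 4137 genes between inflorescence and tendril. With only the libraries of the organs compared, 258 genes differed between tendril and leaf and 5679 had an inflorescence position slope. The difference of the position slopes gave 1 gene with pseudocount 0.1, 12 with pseudocount 5, 1 with no filter on low values, and with voom 0 (796 at an unadjusted p under 0.05 in limma). The picovine genotype difference gave 11 genes with no filter and 13 with no position term, with prior degrees of freedom of 1.52 and 2.37 instead of 4.80, and 4 residual degrees of freedom instead of 2 in the latter. Under the stricter limit of 0.1, organ-restricted genes numbered 11 in inflorescence, 0 in tendril and 2 in leaf. Gene lists called with an estimated correlation were 0 for inflorescence against tendril, 1 for inflorescence against leaf and 0 for tendril against leaf, the last 1 after quantile normalization. Leaving out each library in turn, the counts ran from 3685 to 7146 for inflorescence against tendril, 1174 to 3254 for inflorescence against leaf, 1159 to 3428 for tendril against leaf, 153 to 4529 for the inflorescence position slope, 0 to 1180 for the tendril position slope, 0 to 170 for the difference of the position slopes and 254 to 2364 for the picovine genotype difference. Organ-restricted genes ran from 42 to 73 in inflorescence, 5 to 38 in tendril and 40 to 89 in leaf. Where a group was left with 1 library, that library is assumed to vary like the others. Without the tendril library of position 1 or 3, comparisons of tendrils with another organ rest on the tendril library of position 2 alone. Fits without a library or with only some organs rest on fewer libraries, and for the other changes the cause was not tested. Of the named genes called, 9 of 56 kept the call in every setting for inflorescence against tendril, 26 of 41 for inflorescence against leaf, 10 of 43 for tendril against leaf, 6 of 33 for the inflorescence slope and 0 of 3 for the slope difference (limma). Depth limits values under 0.198 to 0.408 RPKM, 3 reads on a gene of 1 kilobase.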

Other observations

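The sugar transport and invertase genes called between inflorescences and tendrils went both ways, and camera did not call the list (adjusted p = 0.598). Of 18 transport and invertase genes, 7 were higher and 3 lower in inflorescences than in tendrils (11 called when adjusted over the list alone). SWEET15 had 1 tendril read and a ratio of 3372 (95% counting interval 605 to 133175), and PMT2 averaged 7.14 ± 11.2 RPKM in inflorescences (n = 6) against 5 tendril reads, a ratio of 74.5 (31.9 to 229). Position 3 weighs most in both ratios. From position 1 to 3, SWEET15 averaged 2.02 to 198 RPKM and PMT2 0.476 to 18.9, with 29.2 for PMT2 in 06C021V0046 at position 3. VVSUC27, a sucrose transporter, was lower, with 4.46 ± 2.31 RPKM against 27.2 ± 15.9. No call of the list was left with the genotype block, where the log2 change of SWEET15 went from 4.87 to 5.50 (adjusted p = 0.103), that of PMT2 from 1.92 to 1.46 (0.557) and that of VVSUC27 from -2.31 to 0.06 (0.978). The call of PMT2 ended also without the tendril library of position 1 or 3 (0.0722 and 0.0726). Against leaves, 1 member was higher and 3 lower in inflorescences, and 4 were lower in tendrils. Of 26 CBL and CIPK calcium sensor genes, 6 were higher and 4 lower in inflorescences than in tendrils (11 called when adjusted over the list alone). CBL08 averaged 9.78 ± 1.94 RPKM in inflorescences and 3.08 ± 0.65 in tendrils, and CIPK02 45.5 ± 26.3 and 166 ± 20.8, with log2 changes of 1.40 and -2.10, and with the block 1.26 and -0.77 (adjusted p 0.351 and 0.697), where no call of this list was left.

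Of 15 flavonoid and stilbene genes, 4 were higher and 1 lower in inflorescences than in tendrils. FLS1, a flavonol synthase, averaged 130 ± 21.8 RPKM and 47.4 ± 8.35, and LAR1, a leucoanthocyanidin reductase, 80.3 ± 22.8 and 28.2 ± 20.8, with log2 changes of 1.43 and 1.70, and with the block 1.77 and 1.53 (adjusted p 0.127 and 0.635). Of 11 flavonoid regulators 1 was higher and 2 lower, and of 6 carotenoid genes 1 was higher and 2 lower. All 4 genes of the wall list were called lower, among them PEL, PL1 and GRIP28, and none with the block, where the log2 changes of these 3 were -1.66, -1.92 and -1.81 against -2.23, -1.66 and -1.998 without it (adjusted p 0.577, 0.717 and 0.588). Without the tendril library of position 1 or 3 their adjusted p values were 0.118 and 0.118, 0.323 and 0.326, and 0.295 and 0.296. The estimate of PL1 went from -1.66 to 0.32 without either of these tendril libraries, where the tendril mean is the position 2 library alone (47.5 RPKM). PL1 also missed the threshold without any other 1 library except the tendril library of position 2 (0.0531 to 0.0684). Also lower were 1 of 5 phenylpropanoid and 1 of 5 oxylipin genes. Of 6 MLO genes 2 were higher and 1 lower, and of 3 germin-like genes 0 were called in limma. With the genotype block 0 genes of the flavonoid, flavonoid regulator, carotenoid, wall, phenylpropanoid, oxylipin and MLO lists were called by limma. As whole lists in camera, flavonoid and stilbene genes were called upward with the block (adjusted p 0.562 without it, 0.0285 with it) and photosynthesis genes downward (0.262 and 0.0381). Neither was called without the block by an estimated correlation (adjusted p = 0.761 and adjusted p = 0.661 with an estimated correlation), which was not run with the block. GERA, a germin-like name, had no tendril read and stood at 0.0486, 0.0483 and 185 RPKM at positions 1, 2 and 3 of inflorescences, with a slope that missed the threshold without the first or second replicate of position 3 (0.101 and 0.0635).

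VVGAI1 stood at 38.6, 68.3 and 3.21 RPKM in tendrils of positions 1, 2 and 3, and at 2.10 and 13.6 RPKM in the leaf pools of 06C021V0046 and Pinot Meunier L2. By the limits used for organs, 8 genes were restricted to the 7 picovine libraries and 23 to the 4 Pinot Meunier L2 libraries. LOC100244179, LOC100248634 and GeneID100264741, the first 3 genes of the leaf set, stood at 39.1, 36.4 and 32.0 RPKM in the leaf pool of 06C021V0046 and at 26.8, 26.9 and 22.2 RPKM in that of Pinot Meunier L2. In several other libraries LOC100244179 and GeneID100264741 had the same value, such as 0.440 RPKM in inflorescence position 3 of 06C021V0046. Whether these 3 genes share reads of near-identical copies was not tested.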
